A study of Mus musculus with 10 samples.

How the data were processed

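RNA sequencing of FACS-sorted mouse B lineage cells was read from 10 libraries in 5 groups of 2: wild type control, NF-kB-activated (NIK allele), Notch-activated (Notch2 intracellular allele), doubly activated and lymphoma (both alleles). Total RNA had been purified on Qiagen RNeasy columns and sequenced on Illumina instruments per the labels. The authors deposited 1 file per library with the estimated counts of each transcript, which per the file headers and values were not normalized. The same files hold TPM computed by the authors from counts and effective transcript lengths. The submitters' processing notes name kallisto 0.44.0 and mouse genome build mm10; the transcript release is not given in the sources used here. The labels number the 2 libraries of each group and do not say whether they came from separate animals, and sex is not given in the sources used here.

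Each file lists 88198 transcripts with 16380889 to 23102081 estimated counts in all. Of these 86031 were matched by identifier to GENCODE M21 (GRCm38, positions counted from 1) and summed to 30205 genes, of which 44 share a symbol with another gene. The 2167 unmatched transcripts held 1.09% to 1.38% of the counts and 2.26% to 6.11% of the TPM of a library and were left out of the gene tests. Estimated counts were summed per gene and rounded. TPM served for the effective lengths of an alternative. Between the libraries of a group, chi-square per degree of freedom was 4.68 to 24.4, so the spread exceeded counting error in each group, and intervals and floors given for single libraries cover counting error only.

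Genes were tested with edgeR 4.0.16 (R 4.3.3) after filterByExpr by group (minimum count 10, minimum total 15), which left 15583 genes, with TMM scaling and the robust quasi-likelihood fit of all 10 libraries in 1 model of 5 groups with 5 residual degrees of freedom. The common dispersion gave a biological coefficient of variation of 0.1205. Tests were two-sided, and adjusted p is Benjamini-Hochberg over the genes of a comparison, called at 0.05. The 7 comparisons were each single activation against control, both against control and against each single activation, their interaction, and lymphoma against doubly activated cells. Replicate numbers were not used as a block; across 10 pairs of groups the deviations of the numbered libraries correlated at r = -0.118 to 0.107 over 10376 genes, which are not independent replicates.

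Gene lists for 32 cell types and pathways (616 genes, 586 tested) were written from textbook knowledge before the data were examined, as were the comparisons, tests and most alternatives. Each was tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over 224 list tests, of which 102 were called, 54 upward and 48 downward. With an estimated correlation 0 of these calls held, while 30 list tests had an unadjusted p under 0.05, all 30 among the calls and in the same direction, and fry called 139 lists. Tested members that rose or fell are counted over all genes, and also adjusted over the list alone.

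The genes named were fixed by rule before the data were examined. In each comparison these were the 5 largest rises and 5 largest falls with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the groups, leaving out predicted genes, receptor segments, Y-linked genes and Xist. Added were the 4 members of each called list and 2 of each other list with the smallest p, Map3k14 and Notch2, and in lymphoma 9 lineage genes. Among list members, those that kept their call in every alternative were preferred for printing. Results for some of the genes so chosen are not reported here. Values of single libraries for Col1a2, Dcn, Ngp, S100a8, Csf1r and Hspa1a were chosen after their values were seen, as were the V segment, isotype and Y-linked counts. CPM of genes are TMM-scaled; for a group without a count a fold is given as a lower bound against 3 counts over the group, and with 1 to 3 counts as a ratio with its exact 95% interval.

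Simulating doubly activated against control (15583 genes) recovered 49.3% of 1.5-fold, 79.1% of 2-fold and 89.4% of 4-fold changes. False calls were 4.6%. With no change 1 list passed. Data hold more changes, uneven spread and related genes, so rates may differ. Alternatives were another normalization, other filters, DESeq2 1.42.0, limma-voom, a fit of the compared groups alone, an effective length offset, receptor segments left out, a minimum fold change, a replicate block and each library left out in turn.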

Results

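RNA was sequenced from sorted B lineage cells of C57BL/6 mice in 10 libraries, 2 for each of 5 groups, to ask what joint activation of the NF-kB and Notch pathways does to B cell transformation and plasticity. A Cre recombinase expressed in B cells switched on a Rosa allele of NIK, the kinase encoded by Map3k14 (NF-kB-activated), of the intracellular part of Notch2 (Notch-activated), or both (doubly activated). Control, NF-kB-activated and doubly activated libraries are labelled as marginal zone precursor B cells of the lymph node, Notch-activated ones as marginal zone B cells though their files bear the letters used for precursors, and all 4 groups as pre-malignant. Lymphoma libraries came from lymphoma tissue with both alleles. Depth was 16407353 and 18564306 estimated counts in control, 19267466 and 19247726 in NF-kB-activated, 18864545 and 18802121 in Notch-labelled, 18791698 and 16380889 in doubly activated and 23102081 and 21425408 in lymphoma libraries. Expression is given as CPM, mean ± SD of 2 libraries, and differences as log2 fold change ± SE with adjusted p of edgeR over 15583 genes. No label says that the 2 libraries of a group came from separate animals, so p-values measure only the spread between these libraries.

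The Notch-labelled and the lymphoma libraries stood apart from the rest. Across genes, Pearson correlations of log2 CPM were 0.989 to 0.995 within groups and 0.968 to 0.983 between control, NF-kB-activated and doubly activated libraries, but 0.865 to 0.892 between Notch-labelled and all other libraries and 0.912 to 0.925 between lymphoma and the remaining 3 groups (genes are not independent replicates). Immunoglobulin V segments, which differ from B cell to B cell, were spread over many members in control, NF-kB-activated and doubly activated libraries: the top Ighv or Igkv segment held at most 7.29% of its class (95% Wilson interval 6.76% to 7.86%, Ighv1-26 in doubly activated library 2). In the Notch-labelled libraries Ighv1-55 (chromosome 12, 115208095 to 115208591 in GRCm38) held 92.8% (92.2% to 93.5%) and 93.8% (93.1% to 94.3%) of Ighv counts, and Igkv12-41 (chromosome 6, 69858420 to 69858884) held 92.7% (92.1% to 93.3%) and 94.1% (93.5% to 94.6%) of Igkv counts. In the lymphoma libraries Ighv1-11 (chromosome 12, 114612243 to 114612675) held 92.3% (92.1% to 92.5%) and 92.1% (91.9% to 92.3%), and Igkv17-121 (chromosome 6, 68036812 to 68037318) held 90.8% (90.7% to 91.0%) and 91.7% (91.5% to 91.8%). Some V segments of a family are near-identical, so counts may be split among them, and intervals cover counting error only.

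**Figure D1:**
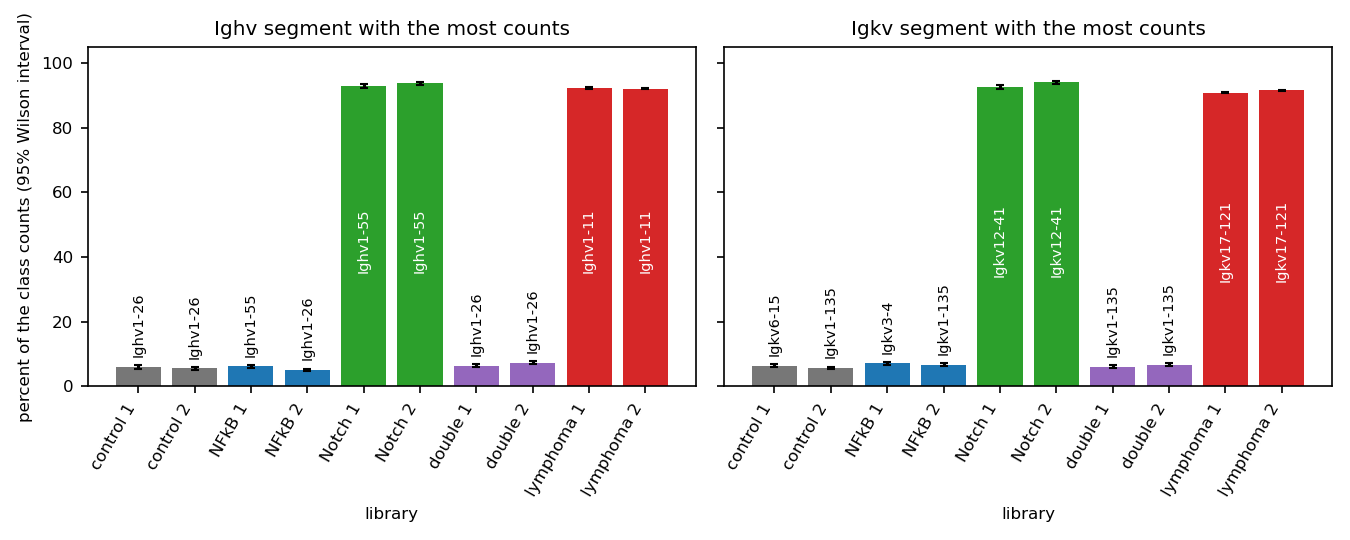
Share of the most counted Ighv segment (left) and Igkv segment (right) in each library, in percent of the counts of its class, with the segment named on or over each bar and 95% Wilson intervals as error bars. The Notch-labelled and lymphoma bars lie between 90.8% and 94.1%, all others at or under 7.29%.

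The activated genes were measured first, since they check the labels. Map3k14 (ENSMUSG00000020941, chromosome 11, 103219762 to 103267472, GRCm38) rose from 116 ± 18.9 CPM in control to 219 ± 2.04 in NF-kB-activated cells (log2 0.91 ± 0.10, adjusted p = 5.98e-05) and 249.5 ± 7.28 in doubly activated cells (log2 1.10 ± 0.10, adjusted p = 1.06e-05); the last 2 groups differed by log2 0.19 ± 0.10 (adjusted p = 0.227). Notch2 (ENSMUSG00000027878, chromosome 3, 98013527 to 98150361) went against the label of the Notch-activated libraries: it fell from 671 ± 27 CPM in control to 281 ± 4.1 there (log2 -1.25 ± 0.08, adjusted p = 9.57e-08). In doubly activated cells it was 728 ± 35.7 CPM (log2 0.12 ± 0.08, adjusted p = 0.376), in lymphoma 167 ± 16.8. Reads of an allele in Rosa and of the endogenous gene fall on the same gene here, and the Notch2 allele covers only the intracellular part, so a gene total is a weak check of it. Heyl, a transcription factor gene induced by Notch, was 0.406 ± 0.0351 CPM in control, 47.5 ± 4.86 in the libraries labelled Notch-activated, 24.5 ± 1.59 in doubly activated and 41.4 ± 3.59 in lymphoma libraries.

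**Figure D2:**
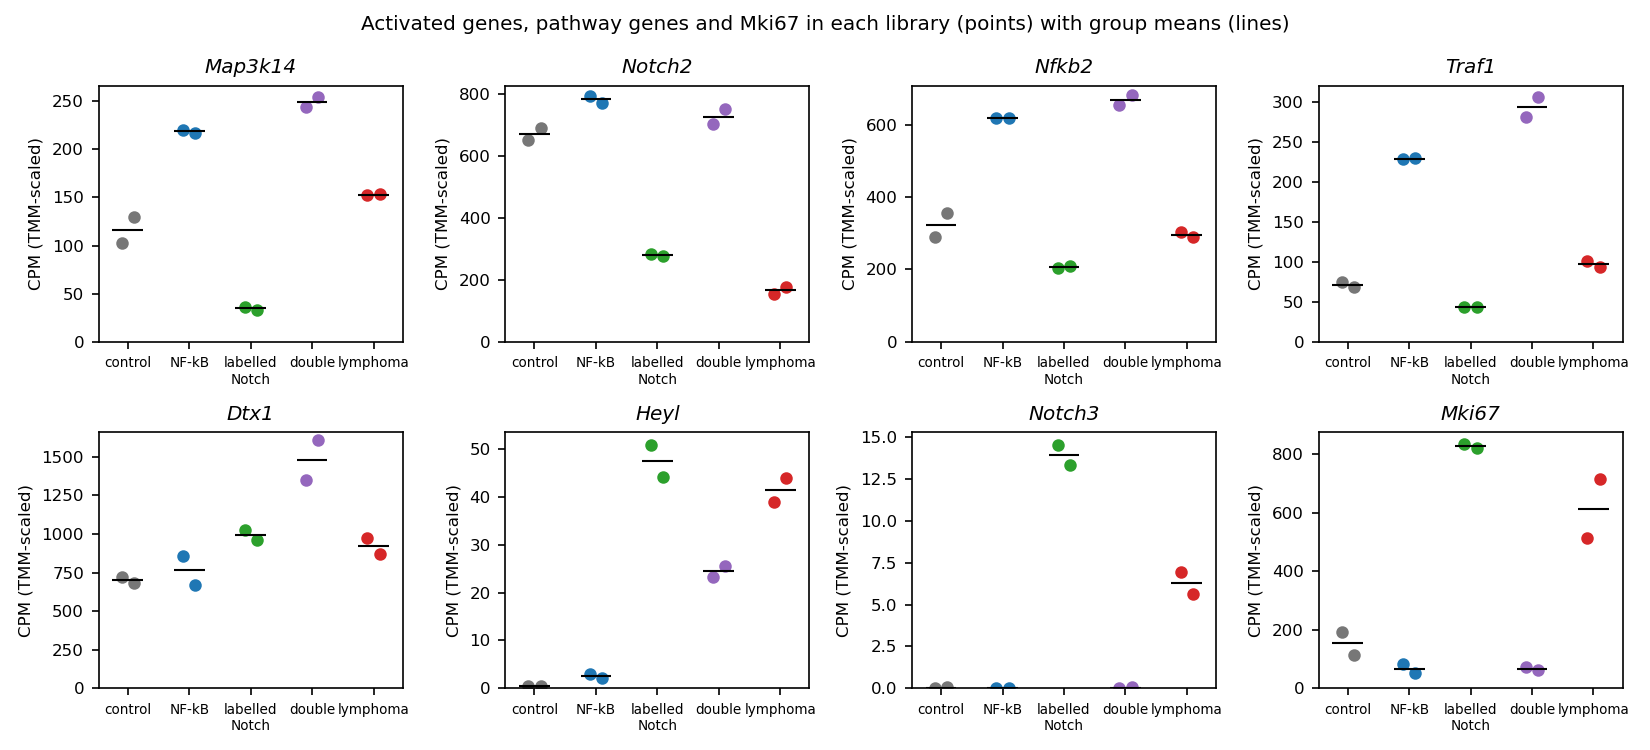
Expression in CPM (TMM-scaled, y axis from 0) of the activated genes Map3k14 and Notch2, the pathway genes Nfkb2, Traf1, Dtx1, Heyl and Notch3 and the proliferation gene Mki67, by group; points are single libraries and lines group means. Notch2 is at 671 ± 27 CPM in control and 281 ± 4.1 CPM in the libraries labelled Notch-activated.

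**Figure D3:**
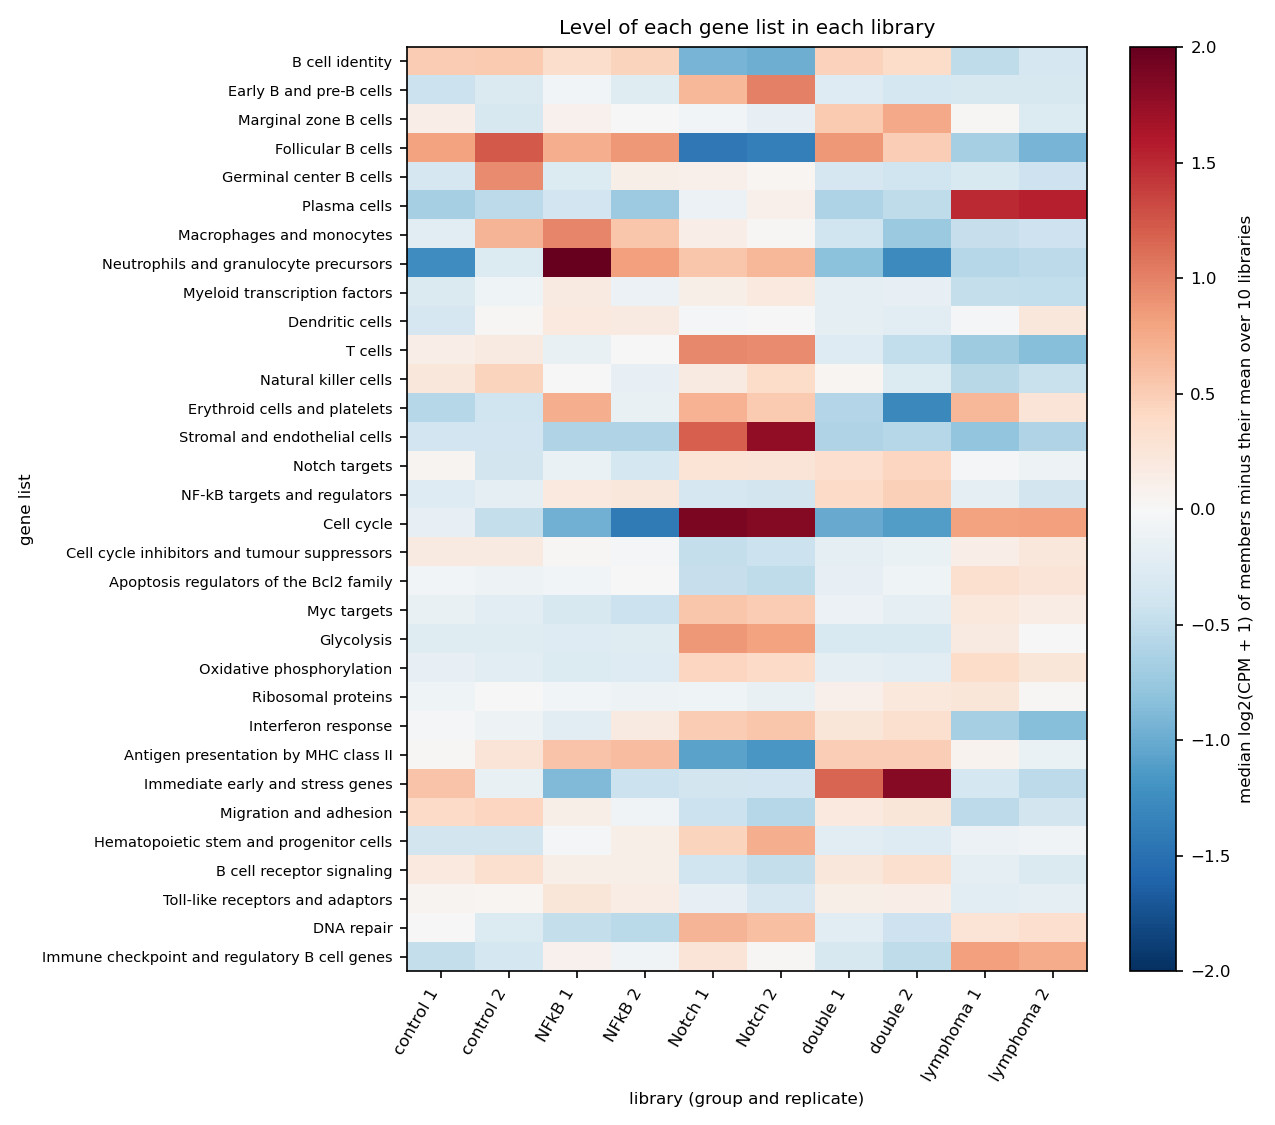
Level of each of the 32 gene lists in each library, as the median over members of log2(CPM + 1) minus the member's mean over the 10 libraries (colour scale from -2 to 2, columns by group and replicate). The lists of plasma cells in lymphoma, cell cycle in Notch-labelled and lymphoma libraries, neutrophils in NF-kB-activated library 1 and immediate early genes in doubly activated libraries stand out.

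NF-kB activation alone was compared with control precursors. The Y-linked gene Ddx3y was at 59.8 and 0.653 CPM in control and 173 and 178 in NF-kB-activated libraries, so sex may differ too. Most NF-kB pathway genes that passed the test rose, and the proliferation genes that passed it fell. Traf1, a TNF receptor adaptor, rose from 71.6 ± 4.45 to 229 ± 0.922 CPM (adjusted p = 7.66e-08); Nfkb2, the precursor of the p52 subunit, rose from 322 ± 47.2 to 619 ± 0.799 CPM, and Nfkbia, the inhibitor of NF-kB, from 136 ± 15.4 to 265 ± 10.1 CPM. Of the largest rises, Cnr1, a cannabinoid receptor, went from 0.232 ± 0.0201 to 169 ± 32.5 CPM (adjusted p = 4.39e-09) and Sspo, the extracellular protein SCO-spondin, from 0.585 ± 0.48 to 381 ± 10.6 CPM. Klhl29 had no count in control and was at least 113-fold higher, taking 3 counts over the control group as its floor, and Kctd15 was 189.7-fold (exact counting interval 52.2 to 1572) higher. Thsd7a reached 51.5 ± 47.2 CPM (adjusted p = 0.00392), with libraries far apart. Among the largest falls, Prag1 went from 78.1 ± 4.85 to 2.73 ± 0.446 CPM (adjusted p = 2.82e-07), Pltp, a phospholipid transfer protein, from 28.2 ± 11.2 to 2.44 ± 0.631 CPM, Endou, an endoribonuclease, from 7.9 ± 1.6 to 0.576 ± 0.0738 CPM, Ngfr, the nerve growth factor receptor, from 5.43 ± 2.02 to 0.524 ± 0.0744 CPM, and Plk2, a polo-like kinase, from 11 ± 9.4 to 0.236 ± 0.111 CPM (adjusted p = 0.0243). In all, 1359 genes rose and 1029 fell, 902 of them by over 2-fold. Without NF-kB-activated library 1 or 2 the count was 1497 or 1435. The call for Thsd7a was lost without control library 1 (0.0554) or 2 (0.0588). The call for Plk2 was lost without NF-kB-activated library 1 (0.147) or 2 (0.162).

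Of the NF-kB targets and regulators, 14 of 31 members rose, 2 fell and 15 did not pass (16 and 3 adjusted over the list alone). Camera called the NF-kB list upward (adjusted p = 8.05e-07, and adjusted p = 0.317 with an estimated correlation). Of the MHC class II presentation genes, 9 of 14 members rose, 1 fell and 4 did not pass (11 and 1 adjusted over the list alone). Camera called the MHC class II list upward (adjusted p = 3.43e-05, and adjusted p = 0.445 with an estimated correlation). The costimulator Cd80 rose from 0.982 ± 0.00339 to 11.4 ± 0.636 CPM and the class II transactivator Ciita from 475 ± 33.8 to 764 ± 4.99 CPM, while the costimulator Cd86 fell from 46.8 ± 3.19 to 27.7 ± 0.542 CPM. Of the cell cycle genes, 0 of 32 members rose, 24 fell and 8 did not pass (0 and 29 adjusted over the list alone). Camera called the cell cycle list downward (adjusted p = 1.91e-14, and adjusted p = 0.445 with an estimated correlation). The mitotic transcription factor Foxm1 fell from 24.8 ± 3.41 to 13.7 ± 1.78 CPM and the replication helicase subunit Mcm5 from 86.3 ± 6.58 to 51.1 ± 7.92 CPM. In DNA repair, 0 rose and 8 fell of 23 (2 and 12 adjusted over the list alone). Camera called the DNA repair list downward (adjusted p = 0.00155, and adjusted p = 0.526 with an estimated correlation). Fanca, a Fanconi anaemia gene, was at log2 -1.38 ± 0.13. In Myc targets, 0 rose and 5 fell of 29 (0 and 6 adjusted over the list alone). Camera called the Myc target list downward (adjusted p = 0.00292, and adjusted p = 0.517 with an estimated correlation). The transferrin receptor Tfrc was at log2 -0.90 ± 0.11. In B cell receptor signalling, 1 rose and 8 fell of 21 (2 and 10 adjusted over the list alone). Camera called the B cell receptor list downward (adjusted p = 0.00447, and adjusted p = 0.517 with an estimated correlation). In immediate early and stress genes, 0 rose and 4 fell of 18 (0 and 5 adjusted over the list alone). Camera called the immediate early list downward (adjusted p = 1.16e-04, and adjusted p = 0.517 with an estimated correlation). Ier2 was at log2 -1.12 ± 0.14 and Zfp36, a regulator of mRNA decay, at -1.05 ± 0.15. The heat shock gene Hspa1a was at 233.6 CPM in control library 1 and 3.05 in library 2.

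Of the neutrophil genes, 10 of 20 members rose, 0 fell and 10 did not pass (18 and 0 adjusted over the list alone). Camera called the neutrophil list upward (adjusted p = 8.54e-06, and adjusted p = 0.517 with an estimated correlation). The antimicrobial peptide gene Camp was 0.19 ± 0.269 CPM in control and 11.7 ± 7.57 in NF-kB-activated libraries (adjusted p = 0.00591), and the gelatinase Mmp9 0.361 ± 0.336 and 9.07 ± 6.67 (adjusted p = 0.00255). The 10 members that rose were 4.14-fold higher in NF-kB-activated library 1 than in library 2 in the median, whereas 27 B cell identity genes had a median log2 ratio of -0.05. In dendritic cell genes, 3 rose and 0 fell of 13 (3 and 0 adjusted over the list alone). Camera called the dendritic cell list upward (adjusted p = 0.0185, and adjusted p = 0.517 with an estimated correlation), a call lost with the replicate number as a block (0.128), without Notch-labelled library 1 (0.125) or 2 (0.131), or without lymphoma library 1 (0.0777) or 2 (0.059). Their median log2 fold change was -0.08 and their mean 0.78, and the transcription factor Zbtb46 rose from 2.38 ± 1.1 to 40.7 ± 1.65 CPM. In stem and progenitor genes, 4 rose and 2 fell of 17 (7 and 2 adjusted over the list alone). Camera called the progenitor list upward (adjusted p = 0.0375, and adjusted p = 0.362 with an estimated correlation), a call lost with the replicate number as a block (0.0905), without Notch-labelled library 1 (0.0751) or 2 (0.0754), without control library 1 (0.0669), or without lymphoma library 1 (0.0538). The receptor kinase Kit went from 0.915 ± 0.86 to 15.4 ± 0.341 CPM. In immune checkpoint genes, 5 rose and 2 fell of 19 (6 and 2 adjusted over the list alone). Camera called the checkpoint list upward (adjusted p = 0.0233, and adjusted p = 0.362 with an estimated correlation), a call lost without NF-kB-activated library 1 (0.0899), or without control library 1 (0.161). The cytokine subunit Il12a went from 13.2 ± 0.0362 to 56 ± 3.57 CPM. In B cell identity genes, 2 rose and 7 fell of 27 (4 and 9 adjusted over the list alone). The B cell identity list was called downward by camera (adjusted p = 0.0471, and adjusted p = 0.519 with an estimated correlation), a call lost with both Notch-labelled libraries left out (0.0701), with the replicate number as a block (0.0524), without NF-kB-activated library 1 (0.169), or without control library 1 (0.106). The coactivator Pou2af1 rose from 493 ± 24.7 to 1431 ± 95.2 CPM. In cell cycle inhibitors, 2 rose and 5 fell of 17 (2 and 10 adjusted over the list alone). The cell cycle inhibitor list was called downward by camera (adjusted p = 0.0458, and adjusted p = 0.383 with an estimated correlation), a call lost with both Notch-labelled libraries left out (0.0701), without NF-kB-activated library 2 (0.103), or without control library 1 (0.0834). Its median log2 was -0.26 and its mean 0.12.

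**Figure D4:**
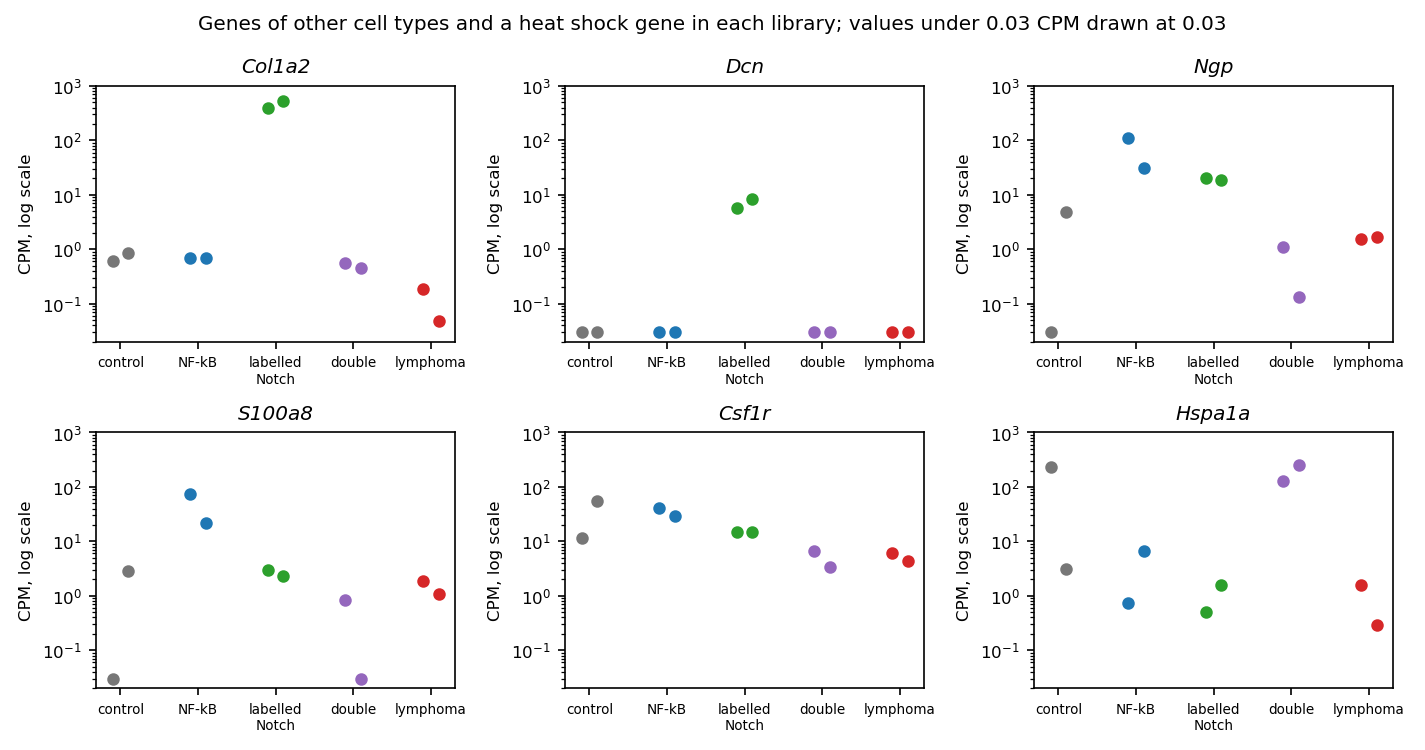
Expression in CPM (TMM-scaled, log axis) of genes of other cell types (Col1a2 and Dcn, stromal; Ngp and S100a8, neutrophil; Csf1r, macrophage) and of the heat shock gene Hspa1a in each library, as points by group; values under 0.03 CPM are drawn at 0.03. Col1a2 is at 391 and 534 CPM in the Notch-labelled libraries, Ngp at 109.2 and 31.7 CPM in the NF-kB-activated ones and Hspa1a at 233.6 and 3.05 CPM in control.

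Doubly activated precursors were compared with control precursors to see both activations before transformation. Of the genes that passed, most NF-kB target, marginal zone and Notch target genes rose, and most cell cycle and follicular genes fell. Heyl rose from 0.406 ± 0.0351 to 24.5 ± 1.59 CPM (adjusted p = 9.86e-09), Dtx1, a Notch-induced ubiquitin ligase, from 699.7 ± 26.9 to 1478 ± 186 CPM, and Asb2, another ubiquitin ligase subunit, from 32.5 ± 3.47 to 395 ± 77.5 CPM. Traf1 rose from 71.6 ± 4.45 to 294 ± 18 CPM (adjusted p = 1.25e-08). Of the largest rises, Fyb2 (at least 189-fold), the transporter Slc47a1 (at least 127-fold) and the sodium iodide symporter Slc5a5 (at least 70.5-fold) had no count in control, Sspo went from 0.585 ± 0.48 to 348 ± 9 CPM and Cnr1 from 0.232 ± 0.0201 to 43.4 ± 9.4 CPM. Among the largest falls, Shisa8 went from 9.88 ± 0.409 to 0.28 ± 0.159 CPM, Kctd14 from 12.5 ± 4.27 to 0.396 ± 0.0876 CPM, the macrophage mannose receptor Mrc1 from 11.6 ± 10.6 to 0.517 ± 0.101 CPM, the transporter Abcc3 from 5.04 ± 5.03 to 0.195 ± 0.276 CPM, and the protease inhibitor Slpi was 72.3-fold (exact counting interval 24.4 to 353) lower. In all, 1641 genes rose and 1449 fell, 1124 of them by over 2-fold. Without doubly activated library 2 the count was 1624, and scaling by library size alone lowered the share of rises among calls from 53.1% to 41.7%. The call for Abcc3 was lost with the replicate number as a block (0.0591), without control library 2 (0.119), or without doubly activated library 2 (0.136). The call for Slpi was lost without doubly activated library 1 (0.0731) or 2 (0.0515).

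Among NF-kB targets and regulators, 17 of 31 members rose, 3 fell and 11 did not pass (20 and 4 adjusted over the list alone). The NF-kB list was called upward by camera (adjusted p = 1.27e-09, and adjusted p = 0.276 with an estimated correlation). The apoptosis inhibitor Bcl2a1b rose from 30.8 ± 1.73 to 89.2 ± 0.958 CPM, while Cd83, an activation marker, fell from 183 ± 6.31 to 79 ± 8.25 CPM. Among marginal zone B cell genes, 9 of 21 members rose, 3 fell and 9 did not pass (11 and 4 adjusted over the list alone). Camera called the marginal zone list upward (adjusted p = 9.89e-06, and adjusted p = 0.488 with an estimated correlation). S1pr3, a receptor for sphingosine phosphate, rose from 100.4 ± 18.3 to 247 ± 13.4 CPM and Tbc1d9 from 31.5 ± 5.46 to 144 ± 18.5 CPM. Of the Notch targets, 5 rose and 2 fell of 17 (5 and 3 adjusted over the list alone). Camera called the Notch target list upward (adjusted p = 4.26e-04, and adjusted p = 0.309 with an estimated correlation), a call lost with the replicate number as a block (0.22), or without Notch-labelled library 1 (0.16) or 2 (0.13). Runx3, a transcription factor of this list, rose from 161 ± 2.28 to 302 ± 33.8 CPM. Among interferon response genes, 8 of 25 members rose, 0 fell and 17 did not pass (8 and 0 adjusted over the list alone). Camera called the interferon list upward (adjusted p = 2.66e-04, and adjusted p = 0.517 with an estimated correlation). The GTPase Gbp2 was at log2 1.28 ± 0.11. Among MHC class II presentation genes, 7 rose and 1 fell of 14 (8 and 1 adjusted over the list alone). The MHC class II list was called upward by camera (adjusted p = 0.00405, and adjusted p = 0.517 with an estimated correlation). Cd80 was at log2 3.35 ± 0.28. Among immediate early and stress genes, 7 rose and 2 fell of 18 (8 and 2 adjusted over the list alone). The immediate early list was called upward by camera (adjusted p = 0.00405, and adjusted p = 0.572 with an estimated correlation). The stress factor Atf3 rose from 0.833 ± 0.562 to 59.9 ± 22.5 CPM and Ier2 fell from 88.3 ± 11.1 to 49.3 ± 8.2 CPM. These genes differed between the control libraries too, with a median log2(CPM + 1) that was 0.746 higher in control library 1. In ribosomal protein genes, 7 rose and 0 fell of 32 (9 and 0 adjusted over the list alone). Camera called the ribosomal protein list upward (adjusted p = 0.00397, and adjusted p = 0.726 with an estimated correlation). Its median log2 was 0.24.

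Of the cell cycle genes, 0 of 32 members rose, 18 fell and 14 did not pass (0 and 25 adjusted over the list alone). By camera, the cell cycle list moved downward (adjusted p = 2.44e-09, and adjusted p = 0.517 with an estimated correlation). Cyclin E1, Ccne1, went from 14.5 ± 0.151 to 5.34 ± 1.26 CPM. Of the follicular B cell genes, 1 of 15 members rose, 7 fell and 7 did not pass (1 and 10 adjusted over the list alone). Camera called the follicular list downward (adjusted p = 3.81e-04, and adjusted p = 0.445 with an estimated correlation). The interleukin 4 receptor Il4ra fell from 261 ± 36.9 to 123 ± 8.98 CPM and the integrin Itgb7 from 183 ± 46.7 to 61.5 ± 2.14 CPM, while Gpr183, an oxysterol receptor, rose from 73 ± 12.6 to 164 ± 19 CPM. In T cell genes, 1 rose and 7 fell of 22 (2 and 10 adjusted over the list alone). Camera called the T cell list downward (adjusted p = 0.0088, and adjusted p = 0.517 with an estimated correlation). The receptor constant gene Trbc2 was at 6.22 ± 0.359 CPM in control and 2.2 ± 0.43 in doubly activated libraries. In germinal centre genes, 1 rose and 5 fell of 14 (2 and 5 adjusted over the list alone). Camera called the germinal centre list downward (adjusted p = 0.0163, and adjusted p = 0.659 with an estimated correlation), a call lost without control library 2 (0.325). The transcription factor Lmo2 went from 171 ± 19.4 to 61 ± 4.17 CPM. In macrophage genes, 4 rose and 7 fell of 28 (4 and 13 adjusted over the list alone). Camera called the macrophage list downward (adjusted p = 0.0177, and adjusted p = 0.714 with an estimated correlation), a call lost without control library 2 (0.226). Adgre1, the F4/80 antigen, went from 13.1 ± 8.38 to 1.95 ± 0.629 CPM. Csf1r, the macrophage growth factor receptor, was 11.5 and 56.2 CPM in the 2 control libraries. In DNA repair, 1 rose and 9 fell of 23 (2 and 9 adjusted over the list alone). The DNA repair list was called downward by camera (adjusted p = 0.0222, and adjusted p = 0.632 with an estimated correlation), a call lost without control library 1 (0.273), or without doubly activated library 2 (0.0859). In cell cycle inhibitors, 2 rose and 5 fell of 17 (2 and 10 adjusted over the list alone). Camera called the cell cycle inhibitor list downward (adjusted p = 0.0356, and adjusted p = 0.362 with an estimated correlation), a call lost with both Notch-labelled libraries left out (0.0578), without control library 1 (0.106), or without doubly activated library 1 (0.0722).

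What the Notch2 allele added on the NF-kB background was read from doubly activated against NF-kB-activated precursors. Of the genes that passed, most Notch target, marginal zone and immediate early genes rose, and most neutrophil and macrophage genes fell. Heyl rose from 2.54 ± 0.557 to 24.5 ± 1.59 CPM (adjusted p = 8.86e-07), Dtx1 from 763 ± 133 to 1478 ± 186 CPM and Cd1d1, the lipid antigen presenter of marginal zone B cells, from 98.5 ± 4.87 to 194 ± 36.6 CPM. Of the largest rises, Fyb2 went from 0.314 ± 0.000159 to 16.5 ± 2 CPM (adjusted p = 5.72e-06), Rgs1, a regulator of G protein signalling, from 2.1 ± 0.221 to 161 ± 46.8 CPM (adjusted p = 0.00342), Atf3 from 1.34 ± 0.26 to 59.9 ± 22.5 CPM, the AP-1 subunit Fosb from 6.44 ± 2 to 799 ± 343 CPM and Plk2 from 0.236 ± 0.111 to 25.2 ± 11.8 CPM. The largest falls were mostly neutrophil genes: Camp (at least 129.5-fold lower) and Cd177 (at least 129-fold), both without a count in doubly activated libraries. Chil3 was 299-fold (exact counting interval 82.5 to 2476) lower, Lcn2 249-fold (exact counting interval 84.8 to 1208) and, outside this group, Wipf3 119-fold (exact counting interval 32.7 to 990.3). In all, 1031 genes rose and 1134 fell, 779 of them by over 2-fold. The count was 1067 or 975 without NF-kB-activated library 1 or 2 and 725 without doubly activated library 2, and scaling by library size alone took the share of rises from 47.6% to 34.0%. The call for Fosb was lost without NF-kB-activated library 1 (0.111) or 2 (0.108), or without doubly activated library 2 (0.0779). The call for Plk2 was lost without NF-kB-activated library 1 (0.0953) or 2 (0.108). The call for Cd177 was lost with the replicate number as a block (0.0516), without Notch-labelled library 1 (0.0666) or 2 (0.0699), without doubly activated library 1 (0.0776) or 2 (0.114), or without lymphoma library 1 (0.0517) or 2 (0.0514). The call for Chil3 was lost with the replicate number as a block (0.0608), without NF-kB-activated library 1 (0.0511), without Notch-labelled library 1 (0.071) or 2 (0.0723), without doubly activated library 1 (0.128) or 2 (0.205), or without lymphoma library 1 (0.0517) or 2 (0.0513). The call for Lcn2 was lost with the replicate number as a block (0.0745), without NF-kB-activated library 1 (0.101) or 2 (0.0519), without Notch-labelled library 1 (0.0882) or 2 (0.0886), or without doubly activated library 1 (0.14) or 2 (0.228).

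Of the Notch targets, 8 of 17 members rose, 2 fell and 7 did not pass (9 and 2 adjusted over the list alone). The Notch target list was called upward by camera (adjusted p = 1.64e-06, and adjusted p = 0.257 with an estimated correlation). Among marginal zone genes, 11 of 21 members rose, 3 fell and 7 did not pass (13 and 3 adjusted over the list alone). The marginal zone list was called upward by camera (adjusted p = 3.71e-10, and adjusted p = 0.362 with an estimated correlation). Plac8 rose from 123 ± 4.32 to 339.7 ± 27.7 CPM, while Gpr174, a lysophospholipid receptor, fell from 139.8 ± 24.9 to 54.3 ± 4.21 CPM. Of the immediate early and stress genes, 11 of 18 members rose, 1 fell and 6 did not pass (13 and 1 adjusted over the list alone). By camera, the immediate early list moved upward (adjusted p = 1.11e-16, and adjusted p = 0.309 with an estimated correlation). Zfp36 rose from 223 ± 23.1 to 719 ± 169 CPM and the orphan nuclear receptor Nr4a1 from 38.2 ± 2.28 to 339.6 ± 129.8 CPM. Among interferon response genes, 11 of 25 members rose, 0 fell and 14 did not pass (12 and 0 adjusted over the list alone). The interferon list was called upward by camera (adjusted p = 3.72e-06, and adjusted p = 0.445 with an estimated correlation). In Myc targets, 9 rose and 1 fell of 29 (12 and 1 adjusted over the list alone). The Myc target list was called upward by camera (adjusted p = 5.85e-04, and adjusted p = 0.513 with an estimated correlation). In ribosomal protein genes, 5 rose and 0 fell of 32 (11 and 0 adjusted over the list alone). The ribosomal protein list was called upward by camera (adjusted p = 1.80e-05, and adjusted p = 0.572 with an estimated correlation). Its median log2 was 0.24. In B cell receptor signalling, 5 rose and 1 fell of 21 (5 and 1 adjusted over the list alone). By camera, the B cell receptor list moved upward (adjusted p = 0.0398, and adjusted p = 0.572 with an estimated correlation), a call lost with both Notch-labelled libraries left out (0.0682), without NF-kB-activated library 1 (0.0686) or 2 (0.0715), or without doubly activated library 1 (0.0532) or 2 (0.0529).

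Of the neutrophil genes, 0 of 20 members rose, 17 fell and 3 did not pass (0 and 19 adjusted over the list alone). The neutrophil list was called downward by camera (adjusted p = 3.05e-10, and adjusted p = 0.445 with an estimated correlation). The members that rose in the single NF-kB activation differed 4.14-fold between the NF-kB-activated libraries. Of the macrophage genes, 1 of 28 members rose, 12 fell and 15 did not pass (1 and 22 adjusted over the list alone). The macrophage list was called downward by camera (adjusted p = 2.08e-08, and adjusted p = 0.49 with an estimated correlation). The integrin Itgam went from 10.5 ± 5.56 to 0.393 ± 0.555 CPM. In erythroid and platelet genes, 0 rose and 3 fell of 11 (0 and 4 adjusted over the list alone). Camera called the erythroid list downward (adjusted p = 0.00169, and adjusted p = 0.517 with an estimated correlation). The carbonic anhydrase Car2 went from 5.21 ± 3.15 to 0.442 ± 0.162 CPM. The level of this list, a median of centred log2(CPM + 1), was 0.729 and -0.149 in NF-kB-activated libraries 1 and 2. In germinal centre genes, 0 rose and 5 fell of 14 (1 and 5 adjusted over the list alone). The germinal centre list was called downward by camera (adjusted p = 0.0026, and adjusted p = 0.572 with an estimated correlation). Lmo2 went from 137 ± 6.3 to 61 ± 4.17 CPM. In follicular genes, 2 rose and 5 fell of 15 (3 and 7 adjusted over the list alone). The follicular list was called downward by camera (adjusted p = 0.0216, and adjusted p = 0.519 with an estimated correlation), a call lost with the replicate number as a block (0.0603), or without NF-kB-activated library 2 (0.117). Itgb7 went from 137 ± 13.7 to 61.5 ± 2.14 CPM and the chemokine receptor Cxcr5 from 493 ± 8.14 to 286 ± 70.5 CPM. Notch2 did not pass the test (log2 -0.11 ± 0.08, adjusted p = 0.447).

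The libraries labelled Notch-activated were compared with control precursors. The sources differ on their cell type and their Notch2 level goes against the label. A single V pair, perhaps 1 clone, held at least 92.7% of Ighv and Igkv counts in both libraries. The p-values in comparisons with these libraries therefore do not cover other clones. The differences below are between libraries so labelled. Of the genes that passed, most cell cycle and stromal genes were higher there, and most B cell identity, follicular and MHC class II genes lower. Heyl rose from 0.406 ± 0.0351 to 47.5 ± 4.86 CPM (adjusted p = 4.87e-10). Several of the largest changes had no count in the lower group. These were the collagen genes Col6a1 (at least 477-fold higher) and Col6a3 (at least 385-fold), Igfbp6, which binds insulin-like growth factors (at least 389.5-fold), and Crisp3 (at least 70.8-fold lower). The pseudogenes Rps13-ps2 (at least 1139.8-fold higher) and Rps15a-ps7 (at least 106-fold lower) share reads with their parent genes and are uncertain. The chemokine receptor Ccr6 fell from 107 ± 3.83 to 1.07 ± 0.465 CPM (adjusted p = 1.44e-09), the calcium channel Cacna1i from 176 ± 59.5 to 1.64 ± 0.434 CPM, and Phkg1, a phosphorylase kinase subunit, from 3684 ± 2557 to 15.8 ± 16.6 CPM. In all, 5328 genes rose and 4593 fell, 5415 of them by over 2-fold. Scaling by library size alone gave 5923 and 4027. Dropping genes under 1 CPM in the other 8 libraries, thus mainly rises, gave 4004 and 4447.

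Of the cell cycle genes, 32 of 32 members rose, 0 fell and 0 did not pass (32 and 0 adjusted over the list alone). The cell cycle list was called upward by camera (adjusted p = 1.26e-16, and adjusted p = 0.445 with an estimated correlation). The replication helicase subunit Mcm2 went from 79.2 ± 6.33 to 404 ± 7.56 CPM and the mitotic kinase Plk1 from 10.5 ± 2.01 to 106 ± 5.8 CPM. Of the Myc targets, 25 rose and 1 fell of 29 (26 and 1 adjusted over the list alone). By camera, the Myc target list moved upward (adjusted p = 9.78e-06, and adjusted p = 0.445 with an estimated correlation). In glycolysis, 13 rose and 4 fell of 21 (13 and 4 adjusted over the list alone). Camera called the glycolysis list upward (adjusted p = 3.53e-04, and adjusted p = 0.507 with an estimated correlation). In oxidative phosphorylation, 22 rose and 0 fell of 28 (23 and 0 adjusted over the list alone). Camera called the oxidative phosphorylation list upward (adjusted p = 9.63e-04, and adjusted p = 0.526 with an estimated correlation). In DNA repair, 17 rose and 4 fell of 23 (17 and 4 adjusted over the list alone). By camera, the DNA repair list moved upward (adjusted p = 0.00397, and adjusted p = 0.561 with an estimated correlation). Of the B cell identity genes, 3 of 27 members rose, 23 fell and 1 did not pass (3 and 24 adjusted over the list alone). Camera called the B cell identity list downward (adjusted p = 1.70e-18, and adjusted p = 0.113 with an estimated correlation). The transcription factors Ebf1 fell from 332 ± 26.5 to 46 ± 1.34 CPM and Foxo1 from 272 ± 7.34 to 40.7 ± 0.0783 CPM. Of the follicular genes, 0 rose and 15 fell of 15 (0 and 15 adjusted over the list alone). By camera, the follicular list moved downward (adjusted p = 6.69e-15, and adjusted p = 0.257 with an estimated correlation). The IgE receptor Fcer2a went from 600.3 ± 97 to 10.1 ± 1.03 CPM. In MHC class II presentation, 1 rose and 12 fell of 14 (1 and 12 adjusted over the list alone). By camera, the MHC class II list moved downward (adjusted p = 2.44e-09, and adjusted p = 0.33 with an estimated correlation). H2-Aa went from 2268 ± 195 to 498 ± 29.8 CPM. In B cell receptor signalling, 1 rose and 17 fell of 21 (1 and 18 adjusted over the list alone). The B cell receptor list was called downward by camera (adjusted p = 1.64e-06, and adjusted p = 0.362 with an estimated correlation). The receptor chain Cd79a went from 2016 ± 98.8 to 677 ± 54.9 CPM. In migration genes, 6 rose and 13 fell of 22 (6 and 14 adjusted over the list alone). Camera called the migration list downward (adjusted p = 0.00314, and adjusted p = 0.257 with an estimated correlation).

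Of the stromal genes, 6 of 9 members rose, 2 fell and 1 did not pass (6 and 2 adjusted over the list alone). Camera called the stromal list upward (adjusted p = 2.62e-04, and adjusted p = 0.403 with an estimated correlation). The collagen gene Col1a2 rose from 0.743 ± 0.181 to 463 ± 101 CPM (adjusted p = 2.51e-10) and Col1a1 from 1.83 ± 0.413 to 209.7 ± 39.3 CPM. Between the Notch-labelled libraries the 6 members that rose were 1.46-fold higher in library 2, in the median. Pecam1, an endothelial gene, fell from 304 ± 5.78 to 165 ± 3.25 CPM. Of the Notch targets, 11 rose and 2 fell of 17 (11 and 2 adjusted over the list alone). By camera, the Notch target list moved upward (adjusted p = 0.0088, and adjusted p = 0.445 with an estimated correlation), a call lost without control library 2 (0.11). Of the early B cell genes, 8 rose and 1 fell of 13 (8 and 1 adjusted over the list alone). Camera called the early B cell list upward (adjusted p = 0.0193, and adjusted p = 0.507 with an estimated correlation), a call lost without Notch-labelled library 2 (0.05). Dntt, the terminal transferase of lymphocyte precursors, went from 0.109 ± 0.154 to 39.2 ± 6.7 CPM and the transcription factor Sox4 from 8.47 ± 1.02 to 865 ± 39.3 CPM. Of the T cell genes, 12 rose and 2 fell of 22 (12 and 2 adjusted over the list alone). The T cell list was called upward by camera (adjusted p = 0.0466, and adjusted p = 0.585 with an estimated correlation), a call lost with receptor segments left out (0.117), without Notch-labelled library 2 (0.0546), without control library 1 (0.0968) or 2 (0.066), or without lymphoma library 2 (0.0569). Cd8b1, a chain of the CD8 coreceptor, went from 3.39 ± 0.335 to 33.4 ± 2.61 CPM. Of the interferon response genes, 12 rose and 4 fell of 25 (12 and 4 adjusted over the list alone). By camera, the interferon list moved upward (adjusted p = 0.0281, and adjusted p = 0.632 with an estimated correlation), a call lost with the replicate number as a block (0.0913), without Notch-labelled library 2 (0.101), or without lymphoma library 1 (0.0575). Gbp2 went from 25 ± 1.55 to 287 ± 6.56 CPM.

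What NIK added on the Notch background was asked by setting doubly activated precursors against the libraries labelled Notch-activated. The label, V pair, stromal genes and Y-linked counts of the latter limit this comparison as well. Of the genes that passed, most B cell identity, MHC class II and NF-kB genes were higher in doubly activated libraries and the cell cycle genes lower. Map3k14 was higher by log2 2.84 ± 0.11 (adjusted p = 1.33e-09) and Notch2 by 1.37 ± 0.09 (adjusted p = 4.58e-08). Of the largest rises, Slc47a1 (at least 148-fold) had no count in the Notch-labelled libraries, and Sspo went from 0.744 ± 0.486 to 348 ± 9 CPM. The actin regulator Nhs was 563-fold (exact counting interval 101 to 22275) higher and the peptide hormone gene Adm 747-fold (exact counting interval 134 to 29541). Of the largest falls, Dntt (at least 435-fold lower), Cpe, a carboxypeptidase (at least 676-fold), and Kirrel (at least 451-fold) had no count in doubly activated libraries. Rps15a-ps7 (at least 74.2-fold higher), Rps13-ps2 (at least 1094-fold lower) and Eno1b (at least 891-fold lower) are near-copies of other genes and uncertain. In all, 4822 genes rose and 5180 fell, 5447 by over 2-fold. Scaling by library size alone gave 3837 and 6056. Dropping genes under 1 CPM in the other 8 libraries, thus mainly falls, gave 4665 and 3839. The call for Adm was lost without Notch-labelled library 1 (0.104) or 2 (0.113), or without doubly activated library 1 (0.0512) or 2 (0.0574).

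Of the cell cycle genes, 0 of 32 members rose, 32 fell and 0 did not pass (0 and 32 adjusted over the list alone). By camera, the cell cycle list moved downward (adjusted p = 1.03e-25, and adjusted p = 0.362 with an estimated correlation). Mcm5 went from 418 ± 17.3 to 48.2 ± 6.21 CPM. Further lists moved lower with camera adjusted p of 1.04e-05 to 0.00217 (adjusted p = 0.362 to 0.519 with an estimated correlation). The members that rose and fell, and those adjusted over the list alone, numbered 1 and 23 of 29 (list alone, 1 and 23) in Myc targets, 6 and 13 of 21 (list alone, 6 and 13) in glycolysis, 0 and 21 of 28 (list alone, 0 and 22) in oxidative phosphorylation, 5 and 17 of 23 (list alone, 5 and 17) in DNA repair, 2 and 13 of 22 (list alone, 2 and 13) in T cell genes and 2 and 7 of 9 (list alone, 2 and 7) in stromal genes. Trbc1, a T cell receptor constant gene, fell from 26.3 ± 7.36 to 1.61 ± 0.71 CPM and Col1a1 from 209.7 ± 39.3 to 1.21 ± 0.33 CPM. Of the NF-kB targets, 18 of 31 members rose, 5 fell and 8 did not pass (18 and 5 adjusted over the list alone). By camera, the NF-kB list moved upward (adjusted p = 2.32e-05, and adjusted p = 0.362 with an estimated correlation). Birc3, an inhibitor of apoptosis, went from 101 ± 0.499 to 354 ± 11.5 CPM and Traf1 from 43.6 ± 0.232 to 294 ± 18 CPM. Of the B cell identity genes, 24 of 27 members rose, 3 fell and 0 did not pass (24 and 3 adjusted over the list alone). By camera, the B cell identity list moved upward (adjusted p = 6.73e-16, and adjusted p = 0.139 with an estimated correlation). Ebf1 went from 46 ± 1.34 to 347 ± 14.8 CPM. In MHC class II presentation, 13 rose and 1 fell of 14 (13 and 1 adjusted over the list alone). Camera called the MHC class II list upward (adjusted p = 2.21e-13, and adjusted p = 0.257 with an estimated correlation). H2-Ob went from 133 ± 7.06 to 912 ± 71.5 CPM. Further lists moved higher with camera adjusted p of 4.74e-10 to 0.0163 (adjusted p = 0.266 to 0.761 with an estimated correlation): 10 and 2 of 21 (list alone, 10 and 2) rose and fell in marginal zone genes, 13 and 0 of 15 (list alone, 13 and 0) in follicular genes, 15 and 1 of 21 (list alone, 15 and 1) in B cell receptor signalling, 13 and 1 of 18 (list alone, 14 and 1) in immediate early genes and 22 and 1 of 32 (list alone, 22 and 1) in ribosomal protein genes. The complement receptor Cr2 rose from 110.4 ± 0.625 to 2905 ± 50.5 CPM and the inhibitory receptor Cd22 from 703 ± 24.5 to 1796 ± 117 CPM. In migration genes, 11 rose and 5 fell of 22 (11 and 5 adjusted over the list alone). The migration list was called upward by camera (adjusted p = 0.0111, and adjusted p = 0.309 with an estimated correlation), a call lost with the replicate number as a block (0.0551), or without Notch-labelled library 2 (0.0632).

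Whether the activations add up was tested by the interaction, the effect of both alleles minus the sum of the effects of each on the log scale. It draws on the Notch-labelled libraries and carries the limits of their label, V pair, stromal genes and Y-linked counts. Departures from additivity were called for 7717 genes, 3728 positive and 3989 negative, 4536 of them by over 2-fold. Scaling by library size alone gave 2971 and 4824. Dropping genes under 1 CPM outside the Notch-labelled libraries, thus mainly negative ones, gave 3703 and 3218. Map3k14 (log2 1.93 ± 0.14, adjusted p = 6.25e-07) and Notch2 (log2 1.15 ± 0.12, adjusted p = 8.48e-06) were higher in doubly activated cells than the sum gives. So were Fosb (log2 9.94 ± 1.42), Rgs1 (log2 8.37), the heat shock genes Hspa1a (log2 12.48 ± 3.18, adjusted p = 0.0236) and Hspa1b (log2 8.78 ± 2.58, adjusted p = 0.0382), near-identical copies whose reads cannot be assigned with certainty, and the pseudogene Rps15a-ps7 (log2 11.18 ± 2.20), uncertain for the same reason. Lower than the sum were the lipoxygenase Alox15 (log2 -17.44 ± 3.72, adjusted p = 0.014), the planar polarity gene Vangl1 (log2 -15.38 ± 1.78), the matrix gene Fras1 (log2 -15.29 ± 0.62), the glucosidase Mgam (log2 -14.95 ± 1.57) and Pdgfrb, a growth factor receptor of stromal cells (log2 -14.88 ± 1.89). Alox15, Vangl1, Mgam and Pdgfrb had no count in control, and Rps15a-ps7 none in the Notch-labelled libraries, so their fitted values depend on the prior count and are no fold sizes. The call for Hspa1a was lost with the replicate number as a block (0.0512), without NF-kB-activated library 1 (0.0907) or 2 (0.0692), without Notch-labelled library 1 (0.0986) or 2 (0.0929), without control library 1 (0.0674), or without doubly activated library 2 (0.0613). The call for Hspa1b was lost with the replicate number as a block (0.077), without NF-kB-activated library 1 (0.111) or 2 (0.0642), without Notch-labelled library 1 (0.134) or 2 (0.134), without control library 1 (0.0883), without doubly activated library 1 (0.0712) or 2 (0.0913), or without lymphoma library 1 (0.0698) or 2 (0.0694). The call for Alox15 was lost without NF-kB-activated library 1 (1), or without Notch-labelled library 2 (0.0534).

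Of the B cell identity genes, 21 of 27 members were positive and 2 negative (23 and 2 adjusted over the list alone). Camera called the B cell identity list upward (adjusted p = 9.38e-20, and adjusted p = 0.113 with an estimated correlation). Of the follicular genes, 14 of 15 members were positive and 0 negative (14 and 0 adjusted over the list alone). Camera called the follicular list upward (adjusted p = 2.21e-13, and adjusted p = 0.257 with an estimated correlation). Of the immediate early genes, 14 of 18 members were positive and 0 negative (15 and 0 adjusted over the list alone). Camera called the immediate early list upward (adjusted p = 4.79e-05, and adjusted p = 0.517 with an estimated correlation). The control libraries used here differed on this list by a median log2 of 0.746. Further lists were called upward with camera adjusted p of 4.33e-08 to 0.0178 (adjusted p = 0.257 to 0.761 with an estimated correlation). Positive and negative members numbered 12 and 4 of 21 (list alone, 12 and 4) in marginal zone genes, 12 and 1 of 14 (list alone, 12 and 1) in MHC class II presentation, 17 and 1 of 21 (list alone, 17 and 1) in B cell receptor signalling, 14 and 5 of 22 (list alone, 14 and 5) in migration and 16 and 1 of 32 (list alone, 17 and 1) in ribosomal protein genes. Of the NF-kB targets, 15 of 31 members were positive and 6 negative (16 and 7 adjusted over the list alone). Camera called the NF-kB list upward (adjusted p = 0.0435, and adjusted p = 0.529 with an estimated correlation), a call lost with the replicate number as a block (0.128), without NF-kB-activated library 1 (0.0635) or 2 (0.0578), without Notch-labelled library 1 (0.0921) or 2 (0.13), without control library 2 (0.0796), or without lymphoma library 1 (0.0655) or 2 (0.053). Their median was 0.41 and their mean -0.09. Of the cell cycle genes, 0 of 32 members were positive and 31 negative (0 and 31 adjusted over the list alone). Camera called the cell cycle list downward (adjusted p = 2.31e-15, and adjusted p = 0.445 with an estimated correlation). Of the neutrophil genes, 0 of 20 members were positive and 18 negative (0 and 19 adjusted over the list alone). By camera, the neutrophil list moved downward (adjusted p = 2.62e-04, and adjusted p = 0.561 with an estimated correlation). The members that rose under NF-kB activation alone differed 4.14-fold between the NF-kB-activated libraries, which limits this list here. Further lists were called downward with camera adjusted p of 3.46e-04 to 0.00883 (adjusted p = 0.509 to 0.576 with an estimated correlation): 2 and 20 of 29 (list alone, 2 and 21) in Myc targets, 5 and 14 of 21 (list alone, 5 and 14) in glycolysis, 0 and 19 of 28 (list alone, 0 and 19) in oxidative phosphorylation and 3 and 14 of 23 (list alone, 3 and 14) in DNA repair. Of the T cell genes, 1 of 22 members were positive and 12 negative (1 and 12 adjusted over the list alone). By camera, the T cell list moved downward (adjusted p = 0.0138, and adjusted p = 0.519 with an estimated correlation), a call lost with receptor segments left out (0.0539). Of the early B cell genes, 2 of 13 members were positive and 6 negative (2 and 6 adjusted over the list alone). The early B cell list was called downward by camera (adjusted p = 0.0195, and adjusted p = 0.49 with an estimated correlation), a call lost with the replicate number as a block (0.0652), or without Notch-labelled library 2 (0.105).

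Lymphoma cells were compared with pre-malignant precursors of the same genotype. The plasma cell and cell cycle genes that passed rose, and most follicular, B cell identity, interferon and immediate early genes that passed fell. Of the plasma cell genes, 14 of 15 members rose, 0 fell and 1 did not pass (14 and 0 adjusted over the list alone). Camera called the plasma cell list upward (adjusted p = 1.28e-20, and adjusted p = 0.0978 with an estimated correlation). Xbp1, the transcription factor of the secretory programme, rose from 72.4 ± 3.38 to 666 ± 4.39 CPM (adjusted p = 8.88e-11), and the endoplasmic reticulum genes Creld2 from 24.4 ± 1.39 to 347 ± 16.2 CPM and Derl3 from 6.37 ± 1.7 to 227 ± 1.46 CPM. Of the largest rises, Ccl22, a chemokine that attracts T cells, went from 0.172 ± 0.151 to 313 ± 38.1 CPM (adjusted p = 1.60e-11). Efcab3 (at least 295-fold higher), Cth, an enzyme of cysteine synthesis (at least 202-fold), Erich3 (at least 157-fold) and Nme9 (at least 110.3-fold) had no count in doubly activated libraries. Of the largest falls, Ccr6 was 1761-fold (exact counting interval 602 to 8544) lower, the zinc finger gene Zfp608 988-fold (exact counting interval 338 to 4795) and Nhs 589-fold (exact counting interval 105 to 23298). The pseudogenes Rab11b-ps2 (at least 122-fold lower) and Rbx1-ps (at least 107-fold) are uncertain. In all, 4065 genes rose and 3923 fell, 3747 by over 2-fold. Both lymphoma libraries hold the same V pair and may be 1 clone. No label tells of more than 1 tumour, so p-values do not cover others.

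Of the cell cycle genes, 31 of 32 members rose, 0 fell and 1 did not pass (31 and 0 adjusted over the list alone). The cell cycle list was called upward by camera (adjusted p = 2.61e-13, and adjusted p = 0.488 with an estimated correlation). Cyclin B2, Ccnb2, went from 5.02 ± 0.486 to 43.1 ± 2.63 CPM and Foxm1 from 14.1 ± 0.779 to 51 ± 1.21 CPM. In oxidative phosphorylation, 25 rose and 0 fell of 28 (27 and 0 adjusted over the list alone). The oxidative phosphorylation list was called upward by camera (adjusted p = 2.66e-04, and adjusted p = 0.517 with an estimated correlation). In DNA repair, 13 rose and 3 fell of 23 (15 and 3 adjusted over the list alone). Camera called the DNA repair list upward (adjusted p = 0.00397, and adjusted p = 0.561 with an estimated correlation). In Myc targets, 18 rose and 3 fell of 29 (19 and 3 adjusted over the list alone). Camera called the Myc target list upward (adjusted p = 0.0297, and adjusted p = 0.585 with an estimated correlation). Ccnd2 went from 68.4 ± 19.8 to 588 ± 49.4 CPM. In immune checkpoint genes, 11 rose and 4 fell of 19 (11 and 4 adjusted over the list alone). The checkpoint list was called upward by camera (adjusted p = 0.00637, and adjusted p = 0.289 with an estimated correlation). Of the B cell identity genes, 3 of 27 members rose, 21 fell and 3 did not pass (3 and 21 adjusted over the list alone). The B cell identity list was called downward by camera (adjusted p = 9.46e-09, and adjusted p = 0.257 with an estimated correlation). Cr2 fell from 2905 ± 50.5 to 25.9 ± 3.67 CPM, the transcription factors Pax5 from 218 ± 15.7 to 105 ± 33 CPM and Ebf1 from 347 ± 14.8 to 233 ± 13.6 CPM, and Cd79a from 1568 ± 24.2 to 1147 ± 86.9 CPM, while Vpreb3, a pre-B cell receptor component, rose from 11.2 ± 1.62 to 233 ± 26.6 CPM. Of the follicular genes, 2 rose and 13 fell of 15 (2 and 13 adjusted over the list alone). The follicular list was called downward by camera (adjusted p = 5.67e-12, and adjusted p = 0.257 with an estimated correlation). In B cell receptor signalling, 2 rose and 17 fell of 21 (3 and 17 adjusted over the list alone). By camera, the B cell receptor list moved downward (adjusted p = 5.64e-04, and adjusted p = 0.488 with an estimated correlation). In the interferon response, 4 rose and 15 fell of 25 (4 and 15 adjusted over the list alone). Camera called the interferon list downward (adjusted p = 0.00139, and adjusted p = 0.519 with an estimated correlation). In immediate early genes, 1 rose and 13 fell of 18 (1 and 14 adjusted over the list alone). The immediate early list was called downward by camera (adjusted p = 0.00124, and adjusted p = 0.53 with an estimated correlation). The zinc finger factor Egr3 went from 54.7 ± 2.37 to 13.8 ± 1.89 CPM. The doubly activated libraries stood apart on this list, at a median centred log2(CPM + 1) of 1.164 and 1.815 against 0.572 and -0.156 in control, so the fall need not come from transformation.

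Of the NF-kB targets, 5 rose and 19 fell of 31 (5 and 20 adjusted over the list alone). The NF-kB list was called downward by camera (adjusted p = 0.0083, and adjusted p = 0.517 with an estimated correlation). Its median log2 was -0.61 and its mean -0.07. Traf1 fell from 294 ± 18 to 97.3 ± 5.67 CPM, lymphotoxin, Lta, from 42.3 ± 1.31 to 9.76 ± 1.71 CPM and the receptor Cd40 from 209.6 ± 11.8 to 91.5 ± 4.11 CPM, while Ccl22 rose. Map3k14 fell from 249.5 ± 7.28 to 153 ± 0.455 CPM and Notch2 from 728 ± 35.7 to 167 ± 16.8 CPM. In MHC class II presentation, 2 rose and 9 fell of 14 (2 and 9 adjusted over the list alone). The MHC class II list was called downward by camera (adjusted p = 0.0226, and adjusted p = 0.572 with an estimated correlation), a call lost without lymphoma library 2 (0.0507). In marginal zone genes, 6 rose and 12 fell of 21 (7 and 12 adjusted over the list alone). By camera, the marginal zone list moved downward (adjusted p = 7.34e-04, and adjusted p = 0.517 with an estimated correlation), a call lost with the replicate number as a block (0.11), or without Notch-labelled library 1 (0.0764) or 2 (0.0754). In migration genes, 9 rose and 13 fell of 22 (9 and 13 adjusted over the list alone). By camera, the migration list moved downward (adjusted p = 0.00155, and adjusted p = 0.257 with an estimated correlation), a call lost with the replicate number as a block (0.146), or without Notch-labelled library 1 (0.146) or 2 (0.135). The hyaluronan receptor Cd44 rose from 46.2 ± 2.79 to 177 ± 10.2 CPM.

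Myeloid genes, which bear on the question of plasticity, were not called as groups in lymphoma cells. In myeloid transcription factors 2 rose and 5 fell of 14 (2 and 5 adjusted over the list alone; camera adjusted p = 0.257), in macrophage genes 6 rose and 4 fell of 28 (5 and 4 adjusted over the list alone; camera adjusted p = 0.594) and in neutrophil genes 2 rose and 0 fell of 20 (0 and 0 adjusted over the list alone; camera adjusted p = 0.443). Cebpa, a transcription factor of granulocytes and macrophages, stood at 0.367 ± 0.426 CPM in doubly activated and 0.31 ± 0.0456 in lymphoma libraries (adjusted p = 0.79). Its relative Cebpb stood at 38.7 ± 17.3 and 33.1 ± 3.45 CPM (adjusted p = 0.612), and Csf1r at 5.01 ± 2.28 and 5.25 ± 1.27 CPM (adjusted p = 0.977). Spi1, the factor PU.1 of B and myeloid cells, fell from 97.3 ± 5.11 to 44 ± 0.531 CPM (adjusted p = 2.08e-06). The zinc finger factor Egr2 fell from 23.3 ± 1.79 to 4.89 ± 0.213 CPM (9.12 in control). Mpeg1, a pore-forming protein of macrophages, rose from 171 ± 17.8 to 1086 ± 50.2 CPM (adjusted p = 6.48e-09). Itgam, the CD11b integrin, rose from 0.393 ± 0.555 to 3.45 ± 0.1 CPM (adjusted p = 0.0308), under 5.22 ± 1.92 in control. That call was lost without control library 1 or 2, doubly activated library 1, or lymphoma library 1 or 2.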

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

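All tests in this part were chosen after the results they concern were seen, apart from the interaction test itself.

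A difference between groups was found by the interaction test of edgeR: the difference between doubly and NF-kB-activated libraries was not that between Notch-labelled and control libraries for 7717 genes, which these libraries cannot assign to the alleles. The named ones were Hspa1a (log2 12.48), Rps15a-ps7 (11.18), Fosb (9.94), Hspa1b (8.78), Rgs1 (8.37), Map3k14 (1.93) and Notch2 (1.15) above additivity, and Alox15 (-17.44), Vangl1 (-15.38), Fras1 (-15.29), Mgam (-14.95) and Pdgfrb (-14.88) below it. Without the genes under 1 CPM in the other 8 libraries the count was 6921. Outside the gene tests, ENSMUST00000117472, a transcript that matched no gene, averaged 1374 CPM in lymphoma libraries (1815 and 932) and 313 CPM in control libraries, and 148 unmatched transcripts exceeded 2 times the highest control library.

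The libraries labelled Notch-activated held stromal transcripts (Col1a2 at 391 and 534 CPM, Col1a1 at 182 and 237 CPM, against at most 2.12 CPM in control) beside cell cycle genes and a dominant V pair. If the Notch2 allele raised stromal genes in any B cell, at least 5 of the 9 tested list members should rise in doubly activated cells, and 0 rose, which argues against it as the whole cause. Stromal RNA mixed in at unequal shares, past the FACS sort, is a candidate source. The risen members were higher in library 2 than the 27 B cell identity genes by a log2 median of 0.625. Yet 4 of the 9 genes reach 1 CPM in control. A clonal B cell population may be the other part, since a single segment held at least 92.7% of Ighv and of Igkv counts while in these classes control libraries thinned to as many counts reached at most 6.21%. Whether the samples, their cell type or a label differ from what is stated stays open, and no test of Notch2 activity separates the allele from the endogenous gene.

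In the NF-kB-activated libraries neutrophil genes were high (Ngp at 109.2 and 31.7 CPM, S100a9 at 108.2 and 35.6 CPM). Were they raised by NIK in any B cell, they should rise in doubly activated cells too, and 0 of 20 tested members did, which argues against this. Neutrophil RNA left after the FACS sort in unequal shares may be the source. The risen members exceeded the B cell identity genes by a log2 median of 2.1 between libraries 1 and 2. Of the list, 7 genes reach 1 CPM in control. An effect of NIK alone that the Notch2 allele reverses remains untested.

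Immediate early and heat shock genes were high in doubly activated libraries and uneven in control (Fos at 229.8 and 84.2 CPM, Hspa1a at 233.6 and 3.05 CPM). Handling may contribute but is untested. Control libraries differed by median log2 0.746 over 18 list genes, but in Ddx3y and Csf1r too. The 10000 random lists, all lower, hold unrelated genes, no test of handling. A Notch2 allele effect cannot be told from it. The list was at a log2 median of -1.04 in lymphoma against control (bootstrap interval -1.52 to 0.361, including 0) and -0.771 in Notch-labelled libraries. An effect of both alleles before transformation is untested too.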

How the results depend on the processing

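Scaling by library size alone, leaving out the Notch-labelled libraries, the minimum of 1 CPM in the other 8 libraries and the crossed block were tried only after the results were seen; the remaining alternatives were planned. The counts of changed genes stayed within 1.5 times their value in all alternatives but the following. Against a 2-fold minimum (glmTreat), which asks more of each gene, 290 genes passed in NF-kB-activated against control, 3769 in Notch-labelled against control, 345 in doubly activated against control, 159 against NF-kB-activated and 3790 against Notch-labelled, 2816 in the interaction and 2280 in lymphoma. Fitted alone, the compared groups gave 1984 for doubly and 1601 (within 1.5 times) for NF-kB-activated cells against control. For doubly against NF-kB-activated they gave 2537 (also within) and the length offset 1393 (causes untested). No list call (0) held with an estimated correlation.

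With each library left out in turn, where the lone library of a group is assumed to vary like the others, the count ranged from 1435 (without NF-kB-activated library 2) to 2291 for NF-kB-activated against control, with 1497 without NF-kB-activated library 1. It ranged from 1624 (without doubly activated library 2) to 3081 for doubly activated against control, and from 725 (without doubly activated library 2) to 2800 for doubly activated against NF-kB-activated, with 1067 and 975 without NF-kB-activated library 1 and 2. A replicate block gave 2100, 9621, 2794, 1764, 9672, 7388 and 7635 in the order of the comparisons above and 98 list calls, and the crossed block 2277 and 2991 for the NF-kB-activated and doubly activated cells against control. Without the Notch-labelled libraries the counts were 2048, 2696 and 1739 for the NF-kB-activated, doubly activated and paired comparisons and 7542 in lymphoma, with 50 of 128 list tests called against 54. Without genes under 1 CPM in the other libraries, 8451 and 8504 genes passed on comparing Notch-labelled libraries with control and with doubly activated ones. In the interaction 6921 passed. This filter favours the change of majority in all 3, to 47.4%, 54.9% and 53.5% higher.

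Of 10449 values for 697 results, most picked for their p or fold, 1 counted as reversed. It was Bcl2l11 in doubly activated against control (length offset, log2 0.0545, adjusted p = 0.898, cause untested). Calls weakened in 23 results with that offset, 3 in DESeq2, 10 with the block and 229 of the values with a library left out, where 19 strengthened. With 2 libraries per group, the simulation recovered 49.3% of 1.5-fold changes, so small differences may be missed.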

Other observations

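All counts of single libraries in this part were chosen after the data were seen. In isotype genes, Ighd held 22.0% and 24.7% of constant region counts in control, 12.2% and 14.1% in NF-kB-activated, 8.11% and 3.96% in doubly activated, 1.37% and 1.34% in Notch-labelled and 0.172% and 0.186% in lymphoma libraries. Ighm held 97.0% and 96.8% in lymphoma, and Ighg3 held 7.44% and 7.65% in Notch-labelled libraries.

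Lambda V segments stood at 77.8 and 81.6 CPM, not TMM-scaled, in control, 214.2 and 223 in NF-kB-activated, 217 and 214 in doubly activated, 5.79 and 7.59 in Notch-labelled and 80.8 and 81.2 in lymphoma libraries. Of the T cell genes in lymphoma against doubly activated cells 5 rose and 9 fell of 22, and of the erythroid and platelet genes 4 rose and 0 fell of 11, with no call by camera (adjusted p = 0.953 and 0.170). The Y-linked gene Ddx3y was at 59.8 and 0.653 CPM in the control libraries, 173 and 178 in NF-kB-activated, 109.6 and 187 in doubly activated, 144 and 154 in lymphoma and 2.40 and 1.88 in Notch-labelled libraries.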
